A study of Mus musculus with 8 samples.

How the data were processed

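RNA from whole mouse hearts was measured on 8 one-colour Affymetrix oligonucleotide arrays. The mice were males aged 6 to 8 weeks, either wild type for the metallothionein genes Mt1 and Mt2 (MT+/+) or labelled as carrying inactivated copies of both (MT-/-). Each mouse received doxorubicin (DOX, an anthracycline cancer drug that is toxic to the heart) at 15 mg/kg in 1 injection into the body cavity, or saline, and hearts were taken on day 4. The labels give 4 groups of 2 biological replicates each: MT+/+ with saline, MT+/+ with DOX, MT-/- with saline and MT-/- with DOX. Groups and replicate numbers were taken from the labels. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from 2 µg of it.

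The deposited values are 1 linear intensity (signal) per probe set and array, and per the submitters' processing notes they were made with GCOS 1.4, the Affymetrix array software. The signal algorithm, the scaling target and the detection calls are not given in the sources used here. The table held 45101 probe sets, of which 64 were Affymetrix controls and were left out of every test, which left 45037. Array medians of the deposited intensity lay between 80.0 and 87.4. The means after trimming 2% from each end lay between 171 and 185, and the highest was 8.06% above the lowest. A limit of 5% had been set for keeping the deposited scaling, so the arrays were quantile-normalized.

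Gene names came from the platform's annotation table. It gave 1 symbol for 34958 probe sets, several for 932 and none for 9211. Of the probe sets with 1 symbol, 34754 carried a symbol current in the RefSeq gene table (assembly GRCm38.p6) when matched through the Entrez gene number, 204 had a number that did not match, and 0 symbols needed an update. That table was otherwise used only for the order of genes along a chromosome, and no coordinates were taken from it. No probe set with several symbols was used to name a gene.

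Values were tested as log2(intensity + 16) after normalization, so a log2 change is on that scale and understates changes of dim probe sets. Probe sets at or above their array's median on at least 2 of the 8 arrays were kept, which left 24751, of which 21469 had 1 symbol, covering 13008 genes, and 3282 had several or none. The tests were made with limma 3.58.1 in R 4.3.3 (lmFit on 4 group means over all 8 arrays, then eBayes with a mean-variance trend), with 4 residual degrees of freedom and a prior worth 4.66. There were 7 comparisons: DOX against saline in each genotype and averaged over both, MT-/- against MT+/+ under each treatment and averaged over both, and the interaction, which is the DOX effect in MT-/- minus that in MT+/+. All p-values are two-sided limma values with Benjamini-Hochberg adjustment over the probe sets of a comparison, and the threshold was adjusted p 0.05. An error after ± is the standard error from the limma fit on 2 arrays per group. An exact test of 2 arrays against 2 cannot go below p 0.333, so no test of single values between 2 groups was made.

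For each gene the tested probe set with the highest mean over all arrays stood for it. In each comparison the text names the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose arrays did not overlap between the groups, or the 5 with the smallest p where none passed. For each gene list it names up to 4 members with the smallest p. Mt1, Mt2, Nppa, Nppb, Myh7, Cdkn1a, Top2a, Top2b, Hmox1 and Nqo1 are always given. Members named outside this rule were chosen after their values were seen. There were 40 gene lists, covering pathways and cell type markers, and the lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison. Each list was also tested with an estimated correlation and with fry, a rotation test of whether the genes of a list move in the same direction on balance. None of the camera calls held with the estimated correlation in any of the 7 comparisons, and that value stands beside each call. The design, the tests, the gene lists, the naming rule and 23 alternatives were chosen before the data were examined.

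The tests were run on simulated arrays with the measured means and spreads and no correlation between genes. The spreads were dealt to the probe sets at random, so the link between mean and spread was lost. A structure by replicate number was not simulated either, so the shares below are only a rough guide to the real arrays. Between 4 and 15 unchanged probe sets were called per comparison. Changes of known size were added to 100 of the 24751 probe sets for each size and comparison. Of the changes of 1 log2 unit, 65% were recovered for DOX in MT+/+, 74% for DOX in MT-/-, 86% for DOX averaged, 61% for genotype under saline, 76% for genotype under DOX, 81% for genotype averaged and 23% for the interaction. For changes of 2 log2 units the shares in the same order were 95%, 92%, 99%, 97%, 96%, 96% and 78%.

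The replicate numbers, 1 and 2 in every group, were checked as pairs. Deviations from the group means on arrays with the same number correlated across probe sets at 0.496, 0.542, 0.360, 0.478, 0.459 and 0.457 for the 6 pairs of groups. The numbers were therefore taken to pair the arrays, on the basis of the data and not of the stated design, and a fit with the number as a block was run as an alternative. It had 3 residual degrees of freedom and a prior worth 6.16. The other alternatives changed the pseudocount, the scaling, the filter, the variance moderation, the groups in the fit, the threshold, the list test and the choice of probe set, or left out each array in turn. With 1 array of a group left out, the remaining array was assumed to vary like those of the other groups. No per-sample column of the table was left unused.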

Results

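The series compared mouse hearts that carried working metallothionein genes with hearts labelled as lacking them, 4 days after doxorubicin (DOX) or saline, as a model of DOX cardiomyopathy. Metallothioneins are small zinc-binding proteins that take up metal ions and oxidants. DOX dominated the profiles: the leading component of a principal component analysis held 48.8% of the variance and separated the 4 DOX arrays from the 4 saline arrays, and the next components held 18.0% and 16.7%. Arrays of the same group correlated at 0.976 to 0.984, and arrays of different groups at 0.924 to 0.985. Past adjusted p 0.05 lay 3433 of 24751 probe sets for DOX averaged over genotypes, 224 for genotype averaged over treatments and 0 for the interaction of genotype with DOX.

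Mt1 and Mt2, the genes stated to be inactivated, gave strong signal on the arrays labelled MT-/- and were not called lower there in any comparison. The deposited Mt1 signal was 3722 and 4034 on the MT+/+ saline arrays, 6735 and 9285 on the MT+/+ DOX arrays, 4667 and 5322 on the MT-/- saline arrays, and 12549 and 12850 on the MT-/- DOX arrays. Mt2 read 452 and 485, then 1210 and 2732, then 968 and 1018, then 2218 and 2213, in the same order. The lowest of these signals lay at percentile 90.1 of its array. The type of allele is not given in the sources used here, and the signal alone neither shows nor excludes loss of the proteins. The groups are therefore called by their labels throughout.

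Mt1 rose after DOX in both genotypes, as did Mt2 on average; both genes are switched on by metals, oxidants and glucocorticoids. Mt1 rose by log2 1.02 ± 0.12 in MT+/+ (2.03-fold, adjusted p 0.0072), by 1.34 ± 0.12 in MT-/- (2.54-fold, adjusted p 0.0012) and by 1.18 ± 0.09 averaged (2.27-fold, adjusted p 1.9e-04). Mt2 rose by 1.85 ± 0.30 in MT+/+ (3.61-fold, adjusted p 0.0190) and by 1.49 ± 0.21 averaged (2.80-fold, adjusted p 0.0030). In MT-/- its value of 1.12 ± 0.30 missed the threshold (2.17-fold, adjusted p 0.0634). It passed with the replicate number as a block (0.0173) and with only the compared groups in the fit (0.0090). Without MT+/+ saline 2 the MT+/+ call of Mt1 was lost (adjusted p 0.0564), and that of Mt2 without either MT+/+ saline array (0.106 and 0.0982). Mt2 in MT-/- gained a call without either MT+/+ DOX array (0.0048 and 0.0051). Averaged over treatments Mt1 was higher on MT-/- arrays by log2 0.50 ± 0.09 (1.42-fold, adjusted p 0.0425). That call was lost without any 1 array other than MT+/+ DOX 2 (adjusted p up to 0.172) and under the deposited scaling (0.0579), median centring (0.0542) and eBayes without the trend (0.0934). A further Mt1 probe set lay between percentiles 39.8 and 57.9 with no call in any comparison (genotype -0.23 under DOX and -0.09 averaged), and the mean of both probe sets was +0.21 for this difference (adjusted p 0.404). Mt1 differed by +0.34 under saline (adjusted p 0.512) and +0.66 under DOX (0.108, or 0.0130 blocked and 0.0303 without MT+/+ DOX 2), and Mt2 by +0.95 (0.451), +0.22 (0.948) and, averaged, +0.58 (0.301, or 0.0185 without MT+/+ DOX 2). Mt4 had +0.29 after DOX (adjusted p 0.0820, or 0.0317 blocked), and Mt3 lay between percentiles 7.5 and 21.3 and was not tested.

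**Figure D1:**
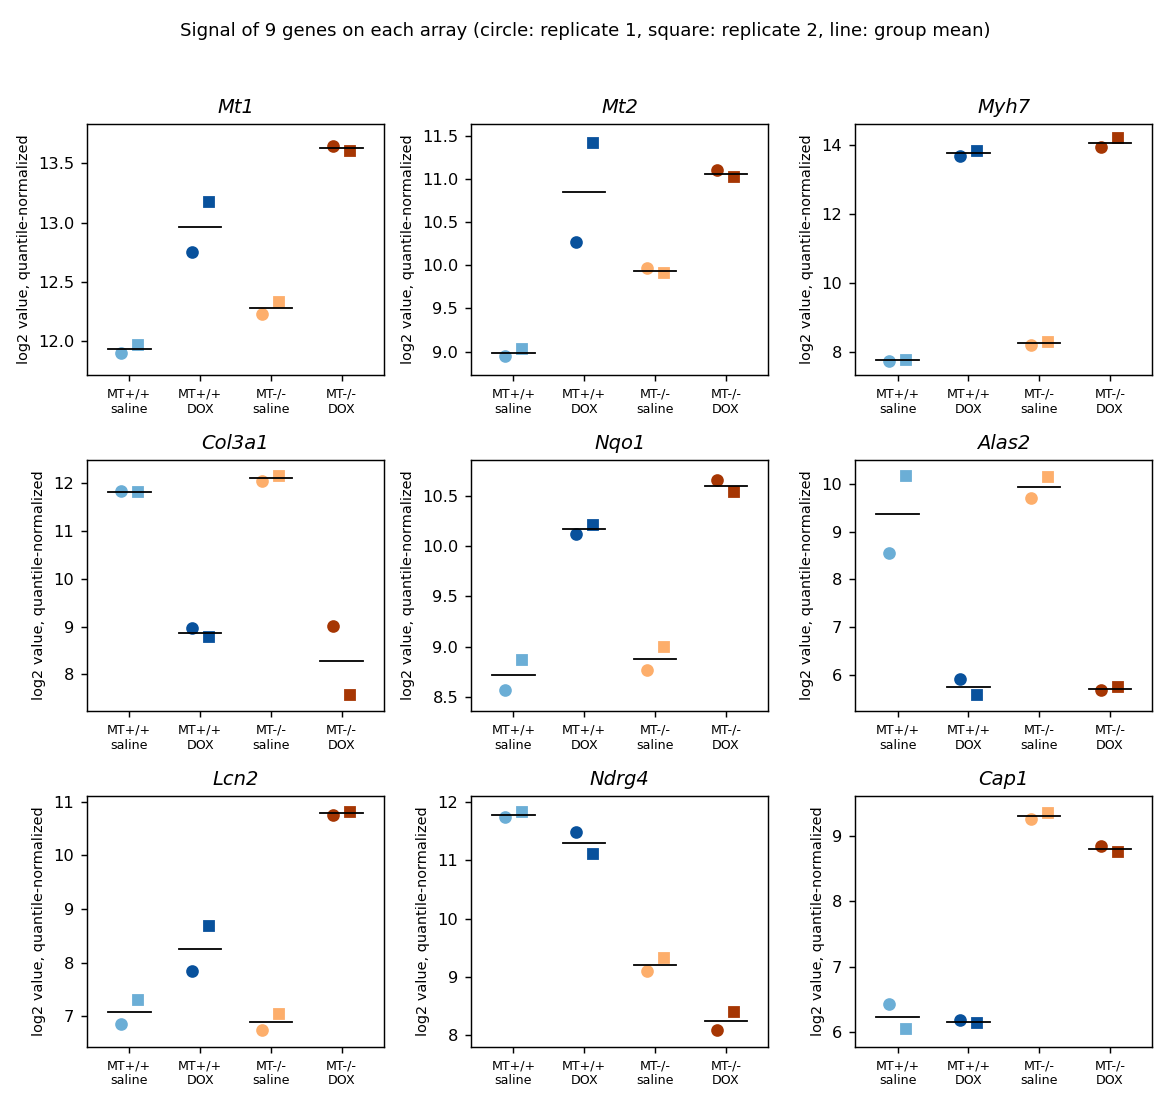
Normalized log2 values of 9 genes on each of the 8 arrays; circles are replicate 1, squares replicate 2, and lines the group means.

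After DOX, averaged over both genotypes, the slow myosin heavy chain Myh7, a gene of fetal and failing heart, rose more than any other. Genes of collagen, the connective tissue scaffold of the heart, fell, as did the red cell haem synthesis gene Alas2 and the vascular receptor Aplnr. The other measured genes of the red cell marker list, Hba-a1, Slc4a1 and Klf1, were not called. Antioxidant genes controlled by the transcription factor NRF2 rose, and so did Fkbp5, a gene switched on by stress steroids, and Cdkn1a, which p53 activates to halt cell division. Of the 24751 probe sets, 1741 were higher and 1692 lower (908 and 1016 genes), or 6702 in all with the replicate number as a block. The count was between 1713 and 3829 with 1 array left out and moved by over 1.5 times without MT+/+ saline 1 (2245), MT+/+ saline 2 (2274), MT+/+ DOX 2 (2046), MT-/- saline 1 (1713), MT-/- saline 2 (1970) or MT-/- DOX 2 (2202).

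The largest rises were those of Myh7 (log2 5.93 ± 0.09, 61.1-fold, adjusted p 9.2e-09), the matricellular growth factor Ccn2 (2.64, 6.25-fold, adjusted p 0.0030), the stress-responsive actin binder Fam107a (2.55, 5.86-fold), the neutrophil iron-trapping protein Lcn2 (2.54, 5.82-fold), Fkbp5 (2.20, 4.60-fold) and the cold-induced RNA binder Cirbp (2.20, 4.59-fold). Next came the sulfotransferase Sult1a1 (2.06, 4.18-fold), the scaffold Cnksr1 (2.02, 4.05-fold), the growth factor binder Igfbp3 (2.01, 4.02-fold) and the proteoglycan Spock2 (1.95, 3.87-fold). On the DOX arrays Myh7 read log2 13.71 to 14.20, near the highest signals of the arrays, so its fold may be understated. The largest falls were those of Alas2 (log2 -3.91 ± 0.30, 15.0-fold, adjusted p 2.1e-04), Aplnr (-3.51, 11.4-fold), the collagen gene Col3a1 (-3.38, 10.4-fold), the splicing factor Srsf6 (-3.36, 10.2-fold) and 2210407C18Rik (-3.11, 8.61-fold), a gene of unknown function. After them came the wound repair gene Nrep (-2.74, 6.67-fold), the globin Hbb-b2 (-2.64, 6.22-fold), the poly(A) polymerase Tent5c (-2.33, 5.02-fold), the collagen gene Col1a1 (-2.32, 4.98-fold) and the antigen presentation gene H2-Aa (-2.21, 4.64-fold). A further Spock2 probe set had +0.12, and of 4 Srsf6 probe sets 2 shared the sign, with others up to +0.18. Cdkn1a rose by 1.37 ± 0.21 (2.59-fold, adjusted p 0.0039), the haem oxygenase Hmox1 by 0.81 ± 0.13 (1.75-fold, adjusted p 0.0061) and the quinone reductase Nqo1 by 1.58 ± 0.11 (adjusted p 1.5e-04). The natriuretic peptide genes missed the threshold, Nppa at +0.47 ± 0.17 (adjusted p 0.112, or 0.0372 without MT-/- DOX 1) and Nppb at +0.67 ± 0.27 (0.150). The topoisomerases that DOX poisons did not pass either, Top2b at 0.00 (0.986) and Top2a at +0.01 (0.980), although another Top2a probe set had -1.35 and the mean of its probe sets passed (-0.67, adjusted p 0.0092). All 25 genes with a call kept it whichever array was left out.

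NRF2 target genes, which make glutathione and clear quinones, rose: of 18 measured, 9 rose and 0 fell, the same adjusted over the list alone. The median was log2 +0.27 (camera adjusted p 2.0e-05, but adjusted p = 0.10 with an estimated correlation). They included Nqo1, the epoxide hydrolase Ephx1 (+1.34), the glutathione transferases Gsta3 (+1.28) and Gstm1 (+0.80), Gclm (+0.69) and the ferritin chain Fth1 (+0.35). The antioxidant enzymes, which remove peroxide and superoxide directly, had no list call: of 17, 2 rose and 7 fell (3 and 8 over the list alone), median -0.09 (adjusted p 0.124). There were rises of the extracellular peroxidase Gpx3 (+1.21) and the thioredoxin inhibitor Txnip (+0.79) and falls of Sod3 (-0.94), Gpx1 (-0.65) and Glrx (-0.79). In the list of metallothionein and zinc transport genes, Mt1 and Mt2 rose and 0 of 15 fell (2 and 0 over the list alone, 3 and 2 blocked). Its median was -0.09 and its mean +0.12, with no call (adjusted p 0.676).

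Extracellular matrix genes, made mostly by fibroblasts, fell: of 24, 19 fell and 1 rose (21 and 1 over the list alone), median -1.02 (camera adjusted p 1.2e-16, but adjusted p = 0.10 with an estimated correlation). Col15a1 (-1.71), Col5a2 (-1.45), Col6a2 (-1.96) and Col6a3 (-1.62) fell along with Col1a1 and Col3a1, and the collagen crosslinking enzyme Lox rose (+0.95). Of 12 fibroblast markers 6 fell and 0 rose (7 and 0 over the list alone). These included Serpinf1 (-1.29), Dpt (-1.40), Pi16 (-1.63) and Mfap5 (-1.07). The median of -0.78 gave adjusted p 9.4e-06 by camera, but adjusted p = 0.189 with an estimated correlation). Macrophage markers fell as well, 11 of 15 with 0 rising (the same over the list alone), median -0.54. Examples were the lysozyme gene Lyz2 (-1.18), the complement genes C1qc (-0.92) and C1qa (-0.70) and the protease Ctss (-0.87) (camera adjusted p 1.3e-06, but adjusted p = 0.10 with an estimated correlation). Because whole hearts were measured, falls of both cell types' markers cannot be told apart from falls inside those cells. Of 20 interferon-induced genes, the antiviral program, 9 fell and 0 rose (14 and 0 over the list alone), median -0.45 (camera adjusted p 4.2e-06, but adjusted p = 0.334 with an estimated correlation). Examples were Gbp3 (-1.38), Gbp2 (-1.01), Rsad2 (-0.68) and Ddx58 (-0.42). Of 16 inflammation genes 3 rose and 2 fell, the same over the list alone, median -0.05 against a mean of +0.26 and no call (adjusted p 0.605). There were rises of Lcn2, Nfkbia (+1.07) and Serpina3n (+1.77) and a fall of the chemokine gene Ccl7 (-0.49).

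Cardiac muscle genes moved both ways. In the list of cardiac stress genes, which the heart takes up again when loaded, 5 of 14 rose and 2 fell (6 and 3 over the list alone), median +0.36, with no call (adjusted p 0.0518). Myh7, Ccn2 and the strain sensor Ankrd1 (+1.47) rose and the skeletal actin gene Acta1 fell (-1.83). Of 21 sarcomere genes 4 rose and 3 fell (5 and 5 over the list alone, 8 and 6 blocked), median -0.01 and mean +0.09 (adjusted p 0.634). Myom2 (+1.34), Tcap (+0.67) and Des (+0.48) rose and the fast myosin heavy chain Myh6 fell (-0.24). Calcium handling genes, which drive each beat, fell: 6 of 18 fell and 1 rose (8 and 2 over the list alone, 9 and 2 blocked), median -0.43 (camera adjusted p 0.0039, but adjusted p = 0.155 with an estimated correlation). The calcium store protein genes Casq2 (-0.79), Hrc (-0.55) and Trdn (-0.53, another probe set +0.05) and the kinase Camk2d (-0.48) fell, while the channel gene Cacna1c rose (+0.45).

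Genes of energy metabolism fell in part. Of 34 genes of oxidative phosphorylation, the mitochondrial ATP supply, 10 fell and 1 rose (14 and 1 over the list alone, 17 and 1 blocked), median -0.15 (camera adjusted p 1.4e-04, but adjusted p = 0.155 with an estimated correlation). Ndufv2 (-0.45), Cyc1 (-0.43) and Uqcrfs1 (-0.30) fell and Ndufv1 rose (+0.32). Of 17 glycolysis genes, which break down glucose, 6 fell and 1 rose (9 and 1 over the list alone), median -0.22 (camera adjusted p 0.0124, but adjusted p = 0.247 with an estimated correlation). Pgk1 (-0.51), Eno3 (-0.50), Pkm (-0.48) and Ldha (-0.24) fell and the glucose carrier gene Slc2a1 rose (+0.91). Fatty acid oxidation, the main fuel route of the adult heart, had no call (adjusted p 0.124): of 22 genes 3 rose and 1 fell (4 and 2 over the list alone, 4 and 3 blocked), median +0.10. Lpl (+0.23), Cd36 (+0.31) and Decr1 (+0.47, another probe set -0.32) rose and Cpt2 fell (-0.41). None of 16 genes of mitochondrial biogenesis passed either way (3 and 3 blocked), median -0.05 (adjusted p 0.728), the nearest being the fusion gene Opa1 (-0.28, adjusted p 0.0713).

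Genes of growth arrest and DNA damage moved in part. Of 19 p53 targets 5 rose and 1 fell (7 and 1 over the list alone), median +0.09 (camera adjusted p 0.0217, but adjusted p = 0.189 with an estimated correlation). Cdkn1a, Perp (+0.90) and Sesn1 (+1.27) rose and Ccng1 fell (-0.72). Cell cycle genes, active in the few dividing cells of the heart, fell: 6 of 20 fell and 0 rose (9 and 0 over the list alone, 9 and 1 blocked), median -0.17 (camera adjusted p 0.0071, but adjusted p = 0.309 with an estimated correlation). They included Mcm6 (-0.73), Ccna2 (-0.85), Cdk1 (-1.23) and Ube2c (-0.93). That call was lost with the stricter filter (adjusted p 0.384). Of 14 apoptosis genes 4 rose and 2 fell, the same over the list alone, median +0.01 with no call (adjusted p 0.392). Bnip3 (+1.39) and the survival gene Bcl2l1 (+1.23) rose and Cycs (-0.27) and Casp8 (-0.41) fell.

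Genes answering to glucocorticoids and fasting, which mark a sick or poorly feeding animal, rose: 12 of 18 rose and 0 fell (13 and 0 over the list alone), median +0.85 (camera adjusted p 1.4e-07, but adjusted p = 0.263 with an estimated correlation). Examples were Fkbp5, Ddit4 (+1.11), Per1 (+1.19) and Zbtb16 (+1.90). Of 12 genes that move with handling and RNA quality 3 rose and 0 fell, the same over the list alone, median +0.35 (camera adjusted p 0.0474, but adjusted p = 0.447 with an estimated correlation): Neat1 (+1.49, another probe set +0.05), Zfp36 (+0.90) and Ier3 (+0.43). That list call was lost without MT+/+ saline 1 (adjusted p 0.0877), MT+/+ DOX 1 (0.0893) or MT-/- saline 1 (0.856, median +0.01), with a pseudocount of 64 (0.0527), the stricter filter (0.0504) and the mean of probe sets (0.0519). The ratio of the 3' to the 5' actin control, which rises as RNA breaks down, was 1.15 and 1.24 under saline and 0.948 and 1.05 under DOX in MT+/+, and 1.14 and 1.23 against 0.914 and 1.18 in MT-/-. The Gapdh ratios lay between 0.984 and 1.05. Of the 16 lists called for DOX averaged, 14 kept the call whichever array was left out. Of 10 neutrophil markers 3 rose and 0 fell, the same over the list alone, median +0.06 with no call (adjusted p 0.133): S100a8 (+1.71), S100a9 (+1.36) and Mmp8 (+0.67). The averaged rises of S100a8 and S100a9 came from MT-/-, as their values in MT+/+ were slightly negative.

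**Figure D2:**
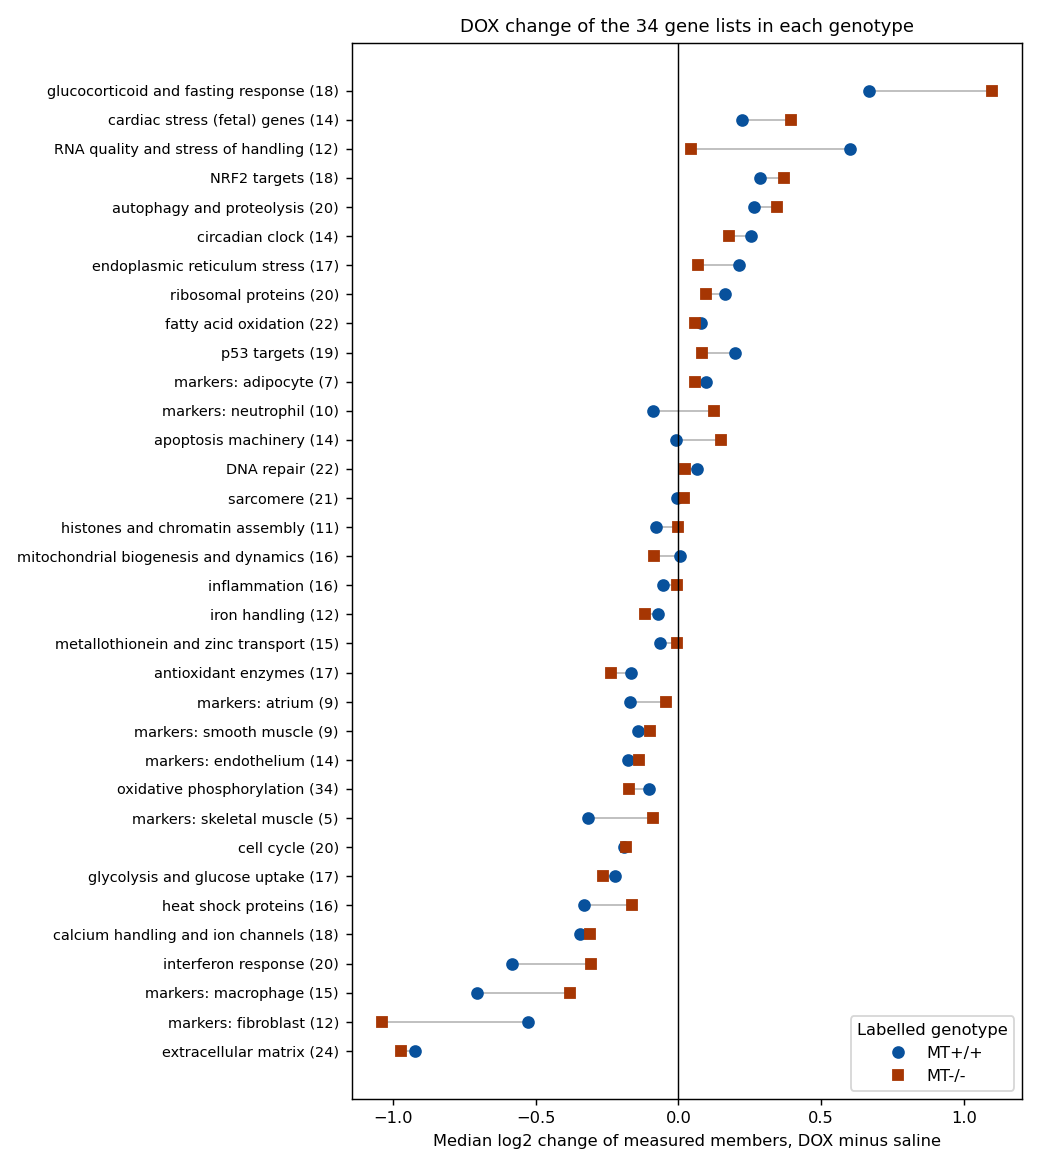
Median log2 change after DOX of the 34 tested gene lists, circles for MT+/+ and squares for MT-/-, with the number of measured genes in parentheses.

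In MT+/+ hearts alone, DOX raised the fetal myosin gene Myh7 and lowered the collagen genes Col1a1 and Col3a1, the globin gene Hbb-b2 and the antigen presentation genes Cd74 and H2-Aa. Past the threshold lay 613 probe sets, 301 higher and 312 lower (161 and 188 genes), or 2740 with the block. The largest rises were Myh7 (log2 6.03 ± 0.12, 65.3-fold, adjusted p 1.6e-07), Cirbp (2.30), Fam107a (2.02), the clock output gene Dbp (1.90), Mt2, Spock2 (1.85, another probe set -0.02), Sult1a1 (1.76), Fkbp5 (1.74), Igfbp3 (1.70) and the sarcomere gene Myom2 (1.51). The largest falls were Alas2 (-3.61, 12.2-fold), Srsf6 (-3.27), Col3a1 (-2.95, 7.72-fold), 2210407C18Rik (-2.91), Hbb-b2 (-2.88), Aplnr (-2.69, 6.44-fold), Nrep (-2.53), Cd74 (-2.25) and H2-Aa (-2.19), which load antigens, and Col1a1 (-2.18). Nqo1 rose by 1.45 ± 0.16 (2.73-fold, adjusted p 0.0061), while Cdkn1a (+0.82, adjusted p 0.195), Hmox1 (+0.44, 0.294), Nppa (+0.45, 0.422), Nppb (+0.36, 0.728), Top2b (+0.04) and Top2a (-0.04, another probe set -1.26) did not pass. Of 22 named genes with a call, 8 (2210407C18Rik, Cirbp, H2-Aa, Hbb-b2, Myh7, Myom2, Nrep and Srsf6) kept it whichever array was left out. Alas2 (0.0617), Cd74 (0.0551) and Nqo1 (0.0532) missed it without MT+/+ DOX 2, Aplnr (0.0564) and Mt1 without MT+/+ saline 2, and Igfbp3 without either of these (up to 0.0564). Col1a1 (up to 0.0761), Col3a1 (0.0747), Fkbp5 (0.0960), Spock2 (0.0846) and Fam107a (0.148) missed it without either MT+/+ saline array or MT+/+ DOX 2. Mt2 missed it without either MT+/+ saline array, and Dbp (up to 0.0564) and Sult1a1 (0.197) without any MT+/+ array. Fam107a (up to 0.0530) and Sult1a1 (0.0565) also missed it without either MT-/- saline array. The count was between 46 and 771: 147 without MT+/+ saline 1, 66 without MT+/+ saline 2, 132 without MT+/+ DOX 1, 46 without MT+/+ DOX 2, 324 without MT-/- saline 1 and 322 without MT-/- saline 2.

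By list, matrix genes fell most in MT+/+ (14 of 24, or 19 over the list alone with Lox rising there, median -0.92, camera adjusted p 1.3e-18, but adjusted p = 0.124 with an estimated correlation). Macrophage markers fell (7 of 15, or 12 alone and 12 blocked, median -0.71, camera adjusted p 1.6e-11, but adjusted p = 0.102 with an estimated correlation), among them C1qa (-1.08), C1qc (-1.15) and Lyz2 (-1.23). Fibroblast markers fell (4 of 12, or 6 alone, median -0.53, camera adjusted p 7.4e-05, but adjusted p = 0.225 with an estimated correlation). Interferon-induced genes were lower as a list (0 of 20 passed, 14 alone, 7 blocked, median -0.58, camera adjusted p 1.3e-08, but adjusted p = 0.287 with an estimated correlation). Glucocorticoid and fasting genes rose (2 of 18, or 6 alone and 9 blocked, median +0.67, camera adjusted p 1.9e-06, but adjusted p = 0.293 with an estimated correlation). NRF2 targets rose (4 of 18, or 6 alone, median +0.29, camera adjusted p 2.4e-04, but adjusted p = 0.134 with an estimated correlation). Cell cycle genes were lower (0 of 20 passed, 5 alone, 4 blocked, camera adjusted p 0.0046, but adjusted p = 0.287 with an estimated correlation, and lost with the stricter filter at 0.233 and with only these groups in the fit at 0.149). Targets of p53 were higher (1 of 19 rose, 3 alone, 5 blocked, camera adjusted p 0.0088, but adjusted p = 0.150 with an estimated correlation). Calcium handling was lower (1 of 18 fell, 4 alone, 6 blocked, camera adjusted p 0.0088, but adjusted p = 0.150 with an estimated correlation). Oxidative phosphorylation was lower (2 of 34 fell, 3 alone, 7 blocked, camera adjusted p 0.0158, but adjusted p = 0.267 with an estimated correlation), and so was glycolysis (1 of 17 fell, 4 alone, 5 blocked, camera adjusted p 0.0221, but adjusted p = 0.277 with an estimated correlation). Fatty acid oxidation was higher (0 of 22 passed, 3 blocked, median +0.08, camera adjusted p 0.0467, but adjusted p = 0.539 with an estimated correlation, and 0.0833 in the blocked fit). The call of fatty acid oxidation was also lost with median centring (0.0620), cyclic loess (0.164), the stricter filter (0.0534), eBayes without the trend (0.114), the mean of probe sets (0.0682) and fry (0.278). The handling and RNA quality list was higher (0 of 12 passed, 2 alone, median +0.60, camera adjusted p 0.0088, but adjusted p = 0.369 with an estimated correlation). Of the 18 lists called, 11 kept the call whichever array was left out. Handling and RNA quality (0.0542), circadian (0.0568) and ER stress genes (0.0542) missed it without MT+/+ DOX 1, glycolysis without MT+/+ DOX 1 (0.0704) or MT+/+ saline 2 (0.235), and oxidative phosphorylation without MT+/+ saline 1 (0.0760). Fatty acid oxidation missed it without MT-/- DOX 1 (0.0525), MT+/+ DOX 1 (0.781) or MT+/+ saline 2 (0.235), and heat shock without MT+/+ DOX 2 (0.0688) or MT+/+ saline 2 (0.0832).

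In MT-/- hearts DOX raised the same myosin gene and, with it, the neutrophil genes S100a8 and S100a9 and the injury genes Lcn2 and Serpina3n. The log2 value of Lcn2 was also higher in MT+/+ on the DOX arrays (7.84 and 8.68) than on the saline arrays (6.84 and 7.30). Past the threshold in MT-/- lay 1538 probe sets, 701 higher and 837 lower (359 and 518 genes), or 4188 with the block. The largest rises were Myh7 (log2 5.84 ± 0.12, 57.2-fold, adjusted p 2.1e-07), Lcn2 (3.90 ± 0.27, 14.9-fold, adjusted p 5.6e-04), S100a8 (3.53 ± 0.50, 11.5-fold, adjusted p 0.0059), Ccn2 (3.24), Fam107a (3.08), S100a9 (2.92 ± 0.41, 7.59-fold, adjusted p 0.0060), Serpina3n (2.90 ± 0.45, 7.49-fold, adjusted p 0.0088), the transporter Slc10a6 (2.68), Fkbp5 (2.66) and the chitinase-like myeloid gene Chil3 (2.64). The largest falls were Aplnr (-4.33), Alas2 (-4.21, 18.5-fold), Col3a1 (-3.81, 14.0-fold), Srsf6 (-3.44), 2210407C18Rik (-3.30), Nrep (-2.95), Tent5c (-2.66), Col1a1 (-2.45), Hbb-b2 (-2.40) and the matrix gene Postn (-2.35, 5.11-fold). Cdkn1a rose by 1.92 ± 0.29 (3.79-fold, adjusted p 0.0082), Hmox1 by 1.17 ± 0.19 (2.26-fold, adjusted p 0.0105) and Nqo1 by 1.72 ± 0.16 (3.29-fold, adjusted p 0.0012), while Nppa (+0.50, 0.302), Nppb (+0.99, 0.189), Top2a (+0.05, another probe set -1.43) and Top2b (-0.03) did not pass. Of 24 named genes with a call 19 kept it whichever array was left out. Without MT-/- saline 1, MT-/- saline 2 or MT-/- DOX 2 Cdkn1a (0.0518, 0.0580 and 0.0536) missed it. So did Ccn2 without either saline array (0.0788 and 0.0524), Hmox1 without MT-/- saline 2 or DOX 2 (0.0841 and 0.0600), Serpina3n without MT-/- DOX 2 (0.0548) and Tent5c without any of the 4 MT-/- arrays (up to 0.150). The count was between 383 and 1994: 383 without MT-/- saline 1, 388 without MT-/- saline 2 and 439 without MT-/- DOX 2.

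In MT-/- matrix genes again had the smallest p of the lists and fell (16 of 24 with Lox rising, or 19 alone, median -0.97, camera adjusted p 7.6e-17, but adjusted p = 0.147 with an estimated correlation). Fibroblast markers fell with them (6 of 12, or 7 alone, median -1.04, camera adjusted p 1.1e-06, but adjusted p = 0.213 with an estimated correlation). Macrophage markers fell (2 of 15, or 4 alone and 6 blocked, median -0.38, camera adjusted p 0.0053, but adjusted p = 0.220 with an estimated correlation). Interferon-induced genes were lower as a list (1 of 20, 1 alone, 3 blocked, median -0.31, camera adjusted p 0.0044, but adjusted p = 0.501 with an estimated correlation). Of 10 neutrophil markers 3 rose (4 blocked, median +0.12, camera adjusted p 0.0130, but adjusted p = 0.220 with an estimated correlation). Glucocorticoid and fasting genes rose (8 of 18, or 14 alone and 13 blocked, median +1.10, camera adjusted p 8.3e-08, but adjusted p = 0.274 with an estimated correlation). NRF2 targets rose (7 of 18, or 10 alone, median +0.37, camera adjusted p 3.1e-06, but adjusted p = 0.147 with an estimated correlation), and so did cardiac stress genes (5 of 14 with 1 falling, the same alone, median +0.39, camera adjusted p 0.0098, but adjusted p = 0.227 with an estimated correlation). Oxidative phosphorylation fell (6 of 34, or 9 alone and 12 blocked, median -0.17, camera adjusted p 4.1e-06, but adjusted p = 0.170 with an estimated correlation). So did calcium handling (3 of 18, or 5 alone and 6 blocked, camera adjusted p 0.0053, but adjusted p = 0.176 with an estimated correlation) and glycolysis (3 of 17, or 7 alone, camera adjusted p 0.0098, but adjusted p = 0.227 with an estimated correlation). Cell cycle genes fell (4 of 20, or 6 alone and 8 blocked, camera adjusted p 0.0161, but adjusted p = 0.392 with an estimated correlation). The handling and RNA quality list had no call here (2 of 12 rose, median +0.04, adjusted p 0.296). Of 15 lists called, 12 kept the call whichever array was left out. The cell cycle missed it without MT-/- DOX 2 (0.0516), MT-/- saline 1 (0.198) or MT+/+ saline 2 (0.0734) and, with its median turned to +0.06, with the stricter filter (0.641). Neutrophil markers missed it without MT-/- DOX 1 (0.236) or MT-/- saline 2 (0.0706) and with the stricter filter (0.0700), and ribosomal genes without MT-/- DOX 1 (0.304).

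Myh7, Col1a1, Col3a1 and Alas2 moved alike in both genotypes. Across 13008 genes the DOX effects correlated at 0.793 (Pearson) and 0.667 (Spearman), with no arrays shared between them, though genes are not independent of one another. Past the threshold in both, 124 genes rose and 158 fell, against 4.44 and 7.49 expected if genes were independent. None was called in opposite directions (6.41 and 5.19 expected). Of the 944 genes called in at least 1 genotype, 98.9% had the same sign in the other. Among the 1924 genes called for DOX averaged, the median ratio of the MT-/- to the MT+/+ change was 1.19. On the leading component MT-/- DOX 2 scored 43.2 and the other DOX arrays 13.9, 20.2 and 24.8. The weight of MT-/- DOX 2 in the ratio was not tested. As no gene passed for the interaction, the larger count of calls in MT-/- is not by itself a difference between genotypes.

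Under saline, hearts labelled MT-/- differed from MT+/+ in few genes. The actin regulator Cap1 was higher and Ndrg4, a gene of heart muscle growth, the cytokine gene Il15 and the phospholipid enzyme gene Plaat1 were lower. Past the threshold lay 46 probe sets, 27 higher and 19 lower (14 and 9 genes), or 209 with the block. The largest rises were Cap1 (log2 3.07 ± 0.15, adjusted p 2.4e-04), Smim10l1 (1.81), the zinc finger gene Zfp991 (1.77, another probe set -1.56), the cilium gene Ift81 (1.5, another probe set -0.28), Ocel1 (1.34), A930005H10Rik (1.33, another probe set -0.05), Frg1 (1.31), the Wnt scaffold Axin1 (1.27, another probe set -0.11), Atp10d (1.18) and the chaperone Calr3 (1.13, another probe set -0.93). The falls were Ndrg4 (-2.57 ± 0.17, 5.94-fold, adjusted p 7.0e-04), Il15 (-2.56 ± 0.18, 5.92-fold, adjusted p 9.9e-04), Plaat1 (-2.18 ± 0.13, 4.53-fold), Mccc1 (-1.37), Adhfe1 (-1.34), Arhgap31 (-1.08), Stk25 (-0.97), Gdpd1 (-0.93) and Pgap2 (-0.92). Nppa (+1.17, adjusted p 0.199), Nppb (+0.40, 0.805), Myh7 (+0.49, 0.310), Cdkn1a (-0.47), Hmox1 (+0.09), Nqo1 (+0.16), Top2a (-0.11) and Top2b (+0.02) did not pass. Of 19 named genes 6 (Cap1, Il15, Ndrg4, Plaat1, Smim10l1 and Zfp991) kept the call whichever array was left out. With the mean of probe sets, however, Smim10l1 (0.0616) and Zfp991 (+0.11, 0.825) missed it, as did A930005H10Rik (0.0616), Mccc1 (0.0616), Pgap2 (0.0791), Ift81 (0.0982), Axin1 (0.239), Gdpd1 (0.255) and Calr3 (0.406). A930005H10Rik (up to 0.190), Arhgap31 (0.318), Atp10d (0.335), Calr3 (0.0988), Gdpd1 (0.294), Ift81 (0.373), Mccc1 (0.166), Ocel1 (0.223), Pgap2 (0.350) and Stk25 (0.306) missed it without any of the saline arrays. Adhfe1 (0.241) and Axin1 (0.0772) missed it without any of them but MT+/+ saline 2, and Frg1 (0.108) without any but MT-/- saline 2. Without either MT+/+ DOX array Adhfe1, Arhgap31, Atp10d, Gdpd1, Ocel1, Pgap2 and Stk25 missed it too (up to 0.0797), as did Ift81 and Pgap2 without either MT-/- DOX array (up to 0.0687). The count was 15 without MT+/+ saline 1, 19 without MT+/+ saline 2, 16 without MT-/- saline 1, 20 without MT-/- saline 2 and at most 50.

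By list, interferon-induced genes were lower in MT-/- under saline (0 of 20 passed, 9 alone, median -0.61, camera adjusted p 3.1e-10, but adjusted p = 0.425 with an estimated correlation). Ifit1 stood at -1.33, Oasl2 at -1.07, Rsad2 at -0.90 and Bst2 at -1.12. Matrix genes were higher (0 of 24 passed, 1 alone, 1 blocked, Mmp2 at +0.91, blocked adjusted p 0.0363, median +0.19, camera adjusted p 9.1e-04, but adjusted p = 0.425 with an estimated correlation). Fibroblast markers were higher (Pi16 at +0.69 and Serpinf1 at +0.44, median +0.31, camera adjusted p 0.0014, but adjusted p = 0.425 with an estimated correlation). So were cardiac stress genes (0 of 14 passed, 3 alone, 1 blocked, Fhl1 at +0.50, blocked adjusted p 0.0378, median +0.35, camera adjusted p 0.0390, but adjusted p = 0.425 with an estimated correlation). Glucocorticoid and fasting genes, with Pdk4 at -0.82 and Zbtb16 at -1.04, were lower (median -0.33, camera adjusted p 4.2e-04, but adjusted p = 0.623 with an estimated correlation). Macrophage markers were lower (median -0.16, camera adjusted p 0.0067, but adjusted p = 0.425 with an estimated correlation) and fatty acid oxidation (median -0.08, camera adjusted p 0.0133, but adjusted p = 0.623 with an estimated correlation). Ribosomal genes were higher (median +0.09, camera adjusted p 0.0238, but adjusted p = 0.623 with an estimated correlation), but not under the deposited scaling, median centring or cyclic loess (0.0976, 0.176 and 0.864). Of these 8 lists only interferon-induced and matrix genes kept the camera call whichever array was left out, and fry called 0 of 34 lists. Cardiac stress missed it without MT-/- saline 1 (0.191) or MT+/+ saline 2 (0.413), fatty acid oxidation without MT-/- saline 2 (0.0830) or either MT+/+ saline array (0.0681 and 0.0610), and glucocorticoid genes without MT+/+ saline 2 (0.117). Fibroblast markers missed it without MT-/- saline 2 (0.0830), macrophage markers without MT-/- saline 1 (0.0506) or MT+/+ saline 2 (0.180), and ribosomal genes without any of the saline arrays (0.0551 to 0.117).

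After DOX, hearts labelled MT-/- had more of the acute phase gene Serpina3n and the neutrophil and injury gene Lcn2, and less of Ucp3 and Pdk4, which serve the burning of fat in muscle. Cap1, Ndrg4, Il15 and Plaat1 differed as they did under saline. Past the threshold lay 70 probe sets, 37 higher and 33 lower (22 and 16 genes), or 383 with the block. The largest rises were Serpina3n (log2 3.36 ± 0.45, 10.2-fold, adjusted p 0.0252), Cap1 (2.65 ± 0.15, 6.26-fold, adjusted p 2.3e-04), Lcn2 (2.53 ± 0.27, 5.76-fold, adjusted p 0.0087), the retinol binder Rbp7 (2.34 ± 0.27, 5.06-fold, adjusted p 0.0119), Zfp991 (1.75, another probe set -1.26), Smim10l1 (1.71, another probe set -0.01), the muscle gene Pdlim3 (1.64), Ahnak2 (1.63), Calr3 (1.49, another probe set -0.81) and Chil3 (1.47). The largest falls were Ndrg4 (-3.06 ± 0.17, 8.33-fold, adjusted p 2.3e-04), Ucp3 (-2.52 ± 0.24, 5.74-fold, adjusted p 0.0045), Il15 (-2.38, 5.22-fold), Plaat1 (-2.36, 5.13-fold), Pdk4 (-1.87 ± 0.25, 3.65-fold, adjusted p 0.0258), Nedd1 (-1.49), the transcription factor Irx3 (-1.47), Mccc1 (-1.25), Pgap2 (-1.21) and Stk25 (-1.08). The peroxidase Gpx3 (+0.79, adjusted p 0.0311), Lox (+1.17, 0.0138) and the acute phase gene Saa3 (+0.99, 0.0258) were higher as well. The neutrophil genes S100a9 (+2.15, 0.113, blocked 0.0342), S100a8 (+2.47, 0.129, blocked 0.0197) and Mmp8 (+0.80, 0.146, blocked 0.0320), Nppa (+1.22, 0.129, blocked 0.0392) and Hmox1 (+0.83, 0.201, blocked 0.0380) passed only in the blocked fit. Nppb (+1.04, 0.558), Myh7 (+0.30, 0.616), Cdkn1a (+0.63), Nqo1 (+0.43), Top2a (-0.02) and Top2b (-0.05) did not pass. Of 20 named genes 7 (Calr3, Cap1, Il15, Ndrg4, Pdlim3, Plaat1 and Zfp991) kept the call whichever array was left out. Zfp991 (+0.24, 0.635), Smim10l1 (0.0885) and Mccc1 (0.0703) missed it with the mean of probe sets. Pdk4 (up to 0.234), Rbp7 (0.122), Serpina3n (0.193) and Stk25 (0.132) missed it without any of the DOX arrays. Chil3 (0.125), Pgap2 (0.112) and Ucp3 (0.0568) missed it without either MT+/+ DOX array, Smim10l1 without MT+/+ DOX 2 (0.0502) and Lcn2 without MT-/- DOX 2 (0.0512). Ahnak2 (0.193) missed it without any DOX array but MT-/- DOX 1, Mccc1 (0.160) without any but MT-/- DOX 2, Irx3 (0.187) without any but MT+/+ DOX 2 and Nedd1 (0.153) without any but MT+/+ DOX 1. Pdk4 and Irx3 also missed it without either MT+/+ saline array (up to 0.0643), and Nedd1 without either MT-/- saline array (up to 0.0513). The count was 23 without MT+/+ DOX 1, 24 without MT+/+ DOX 2, 42 without MT-/- DOX 2 and at most 62.

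By list, cardiac stress genes were higher in MT-/- after DOX (0 of 14 passed, 6 alone, 3 blocked, median +0.47, camera adjusted p 9.1e-07, but adjusted p = 0.127 with an estimated correlation). Ankrd23 stood at +1.03, Fhl1 at +0.60 and Ankrd1 at +0.78. NRF2 targets were higher (0 of 18 passed, 2 alone, 1 blocked, median +0.22, camera adjusted p 2.2e-06, but adjusted p = 0.127 with an estimated correlation). So were macrophage markers (0 of 15 passed, 2 alone, median +0.18, camera adjusted p 2.6e-04, but adjusted p = 0.169 with an estimated correlation). Neutrophil markers were higher (0 of 10 passed, 3 alone, 3 blocked, median +0.10, camera adjusted p 0.0235, but adjusted p = 0.259 with an estimated correlation). The same held for metallothionein and zinc transport genes (0 of 15 passed, 1 alone, 1 blocked, median +0.13, camera adjusted p 0.0390, but adjusted p = 0.259 with an estimated correlation, and 0.0514 in the blocked fit). Autophagy genes were higher (1 alone, median +0.20, camera adjusted p 0.0013, but adjusted p = 0.247 with an estimated correlation). Inflammation genes were called higher (3 of 16, 3 alone, mean +0.44, camera adjusted p 0.0161, but adjusted p = 0.259 with an estimated correlation), although their median was 0.00, and -0.03, -0.02 and -0.00 under the deposited scaling, median centring and cyclic loess. Oxidative phosphorylation genes were lower (median -0.14, camera adjusted p 2.9e-07, but adjusted p = 0.127 with an estimated correlation). Fatty acid oxidation was lower (1 of 22, 2 alone, 3 blocked, median -0.11, camera adjusted p 0.0019, but adjusted p = 0.564 with an estimated correlation), as was mitochondrial biogenesis (median -0.20, camera adjusted p 0.0302, but adjusted p = 0.259 with an estimated correlation, 0.0821 under the deposited scaling and 0.0804 under median centring). Interferon-induced genes were lower (0 of 20, 0 alone, median -0.33, camera adjusted p 7.1e-04, but adjusted p = 0.709 with an estimated correlation). Of the 11 lists called by camera, fry called only NRF2 targets and oxidative phosphorylation. Whichever array was left out, 4 kept the call. Fatty acid oxidation missed it without MT-/- DOX 1 (0.316) or MT+/+ DOX 1 (0.552), inflammation without MT-/- DOX 1 (0.336) or MT+/+ DOX 1 (0.0717), interferon without MT+/+ DOX 2 (0.285) and autophagy without MT+/+ DOX 1 (0.0970). Neutrophil markers missed it without MT-/- DOX 1 (0.472), MT-/- DOX 2 (0.0662) or MT+/+ DOX 1 (0.0809), metallothionein genes without MT-/- DOX 1 (0.336) or MT+/+ DOX 1 (0.106), and mitochondrial biogenesis without MT-/- DOX 2 (0.350) or MT+/+ DOX 1 (0.104).

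Averaged over treatments, Cap1 and Rbp7 were higher and Ndrg4, Il15, Plaat1 and Ucp3 lower in hearts labelled MT-/-. The natriuretic peptide gene Nppa, a sign of load on the heart, was higher too. Past the threshold lay 224 probe sets, 109 higher and 115 lower (52 and 63 genes), or 1202 with the block. The largest rises were Cap1 (log2 2.86 ± 0.10, 7.25-fold, adjusted p 1.8e-05), Rbp7 (2.03 ± 0.19, 4.08-fold), Smim10l1 (1.76), Zfp991 (1.76, another probe set -1.41), Pdlim3 (1.38), Ocel1 (1.32), Calr3 (1.31, another probe set -0.87), the eosinophil chemokine gene Ccl11 (1.26), Atp10d (1.23) and Nppa (1.20 ± 0.17, 2.29-fold, adjusted p 0.0198). The largest falls were Ndrg4 (-2.81 ± 0.12, 7.03-fold, adjusted p 2.0e-05), Il15 (-2.47 ± 0.13, 5.56-fold), Plaat1 (-2.27, 4.82-fold), the complement inhibitor Cd59a (-1.81), Ucp3 (-1.58 ± 0.17, 2.98-fold, adjusted p 0.0048), the glucose uptake gene Tbc1d4 (-1.40), Nedd1 (-1.38), Pdk4 (-1.34), Mccc1 (-1.31) and the interferon-induced gene Rtp4 (-1.18). Nppb (+0.72, 0.324), Myh7 (+0.40, 0.0923, blocked 0.0131), Cdkn1a (+0.08), Hmox1 (+0.46, 0.203, blocked 0.0492), Nqo1 (+0.30), Top2a (-0.07) and Top2b (-0.01) did not pass. Of 21 named genes with a call 14 kept it whichever array was left out, among them Zfp991, which missed it with the mean of probe sets (+0.18, 0.402). Cd59a (up to 0.106) missed it without any MT+/+ array or MT-/- DOX 2, Rtp4 (0.142) without any array but MT+/+ saline 2, Tbc1d4 (0.144) without any but MT+/+ saline 1 and Mt1 without any but MT+/+ DOX 2. Nppa missed it without either MT+/+ DOX array (0.0508 and 0.0934) or either MT-/- saline array (0.0594 and 0.0821), and Pdk4 without either MT+/+ saline array (0.0599 and 0.0521) or MT+/+ DOX 2 (0.0704). Ccl11 missed it without either MT+/+ DOX array (0.0513 and 0.0529) or MT-/- saline 2 (0.0564). The count was 89 without MT+/+ saline 1, 118 without MT+/+ saline 2, 95 without MT+/+ DOX 1, 92 without MT+/+ DOX 2, 101 without MT-/- saline 1, 88 without MT-/- saline 2 and at most 194. Of the called genes, 5 besides Mt1 itself lay within 200 genes of Mt1 in the gene order (assembly GRCm38.p6), Ndrg4, Irx3, Gadd45gip1, Mmp2 and Rnaseh2a. The replicate number differed in more probe sets, 3621, than the genotype did.

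**Figure D3:**
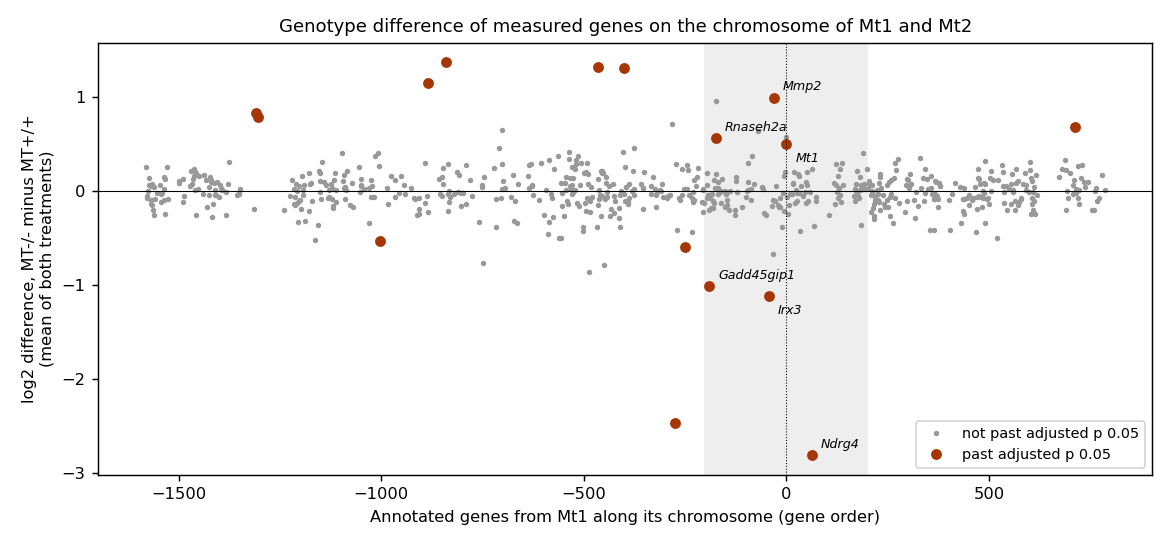
Genotype log2 difference averaged over treatments, by gene order from Mt1 on its chromosome. The grey band holds 200 genes on either side, and the genes with a call are named.

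By list, interferon-induced genes were lower on average (2 of 20, Rsad2 at -0.84 and Oasl2 at -0.94, 9 alone, 7 blocked, median -0.48, camera adjusted p 3.8e-08, but adjusted p = 0.589 with an estimated correlation). NRF2 targets were higher (0 of 18 passed, 4 up and 1 down alone, 4 up blocked, median +0.18, camera adjusted p 7.8e-05, but adjusted p = 0.246 with an estimated correlation). Cardiac stress genes were too (2 of 14, Nppa and Ankrd23 at +0.71, 4 alone, 4 blocked, median +0.39, camera adjusted p 7.8e-05, but adjusted p = 0.246 with an estimated correlation). Matrix genes were higher (2 of 24, Mmp2 at +1.0 and Lox at +0.64, 4 alone, 3 blocked, median +0.11, camera adjusted p 0.0143, but adjusted p = 0.589 with an estimated correlation). So was the metallothionein and zinc list, of which Mt1 alone passed (1 of 15, 1 alone, median +0.09, camera adjusted p 0.0188, but adjusted p = 0.312 with an estimated correlation). Oxidative phosphorylation was lower (0 of 34 passed, 0 alone, 2 blocked, median -0.08, camera adjusted p 7.8e-05, but adjusted p = 0.246 with an estimated correlation). Fatty acid oxidation was lower, with Ucp3 as the member that passed (1 of 22, 3 alone, 2 blocked, median -0.14, camera adjusted p 8.0e-04, but adjusted p = 0.589 with an estimated correlation). Of these 7 lists, matrix genes missed the call without MT-/- DOX 1 (0.275) or MT+/+ DOX 2 (0.112), fatty acid oxidation without MT+/+ DOX 1 (0.0560) and the metallothionein list without MT-/- DOX 1 (0.0939). By fry 4 of the 34 lists were called: NRF2 targets, cardiac stress, oxidative phosphorylation and the metallothionein and zinc list. In the antioxidant enzymes Gpx3 was higher (+0.53, adjusted p 0.0222) and the mitochondrial peroxidase Prdx3 lower (-0.45, adjusted p 0.0458).

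No gene passed for the interaction, so no single gene was called as answering DOX differently in the hearts labelled MT-/-. The values nearest to passing included injury and myeloid genes. Of 24751 probe sets, 573 (2.32%) had unadjusted p below 0.05, or 1723 (6.96%) with the block, and with only 23% of simulated changes of 1 log2 unit found, a count of 0 leaves room for real differences. The 5 genes with the smallest p were Lcn2 (+2.71 ± 0.38, adjusted p 0.901), the myeloid gene Chil3 (+1.59, 0.901), Axin1 (-1.09, 0.901, another probe set +0.21), the kinase gene Map3k6 (+0.98, 0.901) and Ucp3 (-1.89 ± 0.34, 1.0). In the blocked fit Lcn2 alone passed (adjusted p 0.0222), and without MT+/+ saline 1 the count was 1. Mt1 (+0.32), Mt2 (-0.73), Cdkn1a (+1.10), Hmox1 (+0.74), Nppa (+0.05), Nppb (+0.64), Myh7 (-0.19), Nqo1 (+0.27), Top2a (+0.09) and Top2b (-0.07) did not pass. The lists called for the interaction are given with the closing observations.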

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

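The tests of removed Mt1 and Mt2 transcripts, exchanged labels and a strain segment, given below, were chosen only after the result was seen. The results here were marked because a gene list differed by camera in its DOX response between genotypes, although no gene passed.

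Macrophage and neutrophil markers had the 2 smallest p by camera. Macrophage markers had a median difference of log2 0.349, with 15 of 15 positive (medians -0.71 in MT+/+ and -0.38 in MT-/-, camera adjusted p 1.6e-09, but adjusted p = 0.138 with an estimated correlation and 0.173 by fry). Neutrophil markers had a median difference of 0.196, with 8 of 10 positive (medians -0.09 and +0.12, camera adjusted p 8.0e-05, but adjusted p = 0.218 with an estimated correlation and 0.197 by fry). S100a8 and S100a9, the main calcium-binding proteins of neutrophils, stood at +3.64 and +3.13 for the difference, having -0.11 and -0.20 in MT+/+, and neither passed (adjusted p 1.0 for both). Fibroblast markers went the other way, with a median difference of -0.390 and 2 of 12 positive (medians -0.53 and -1.04, camera adjusted p 4.4e-04, but adjusted p = 0.328 with an estimated correlation and 0.440 by fry). These 3 lists kept the camera call whichever array was left out.

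Stress and defence genes differed upwards. Glucocorticoid and fasting genes had the largest median difference, 0.431 (14 of 18 positive, medians +0.67 and +1.10, camera adjusted p 0.0016, but adjusted p = 0.633 with an estimated correlation). The call was lost without MT-/- DOX 2 (0.402), MT+/+ DOX 1 (0.170) or MT+/+ saline 2 (0.132). Interferon-induced genes had 0.267 (18 of 20 positive, medians -0.58 and -0.31, camera adjusted p 0.0018, but adjusted p = 0.722 with an estimated correlation), lost without MT-/- DOX 1 (0.0707), MT+/+ DOX 1 (0.437) or MT+/+ saline 1 (0.816). Cardiac stress genes had 0.190 (11 of 14 positive, medians +0.22 and +0.39, camera adjusted p 0.0109, but adjusted p = 0.328 with an estimated correlation), lost without MT-/- DOX 2 (0.134), MT+/+ DOX 2 (0.101) or MT+/+ saline 1 (0.0813). Autophagy and proteolysis genes had 0.172 (15 of 20 positive, medians +0.27 and +0.34, camera adjusted p 0.0047, but adjusted p = 0.284 with an estimated correlation), lost without MT+/+ DOX 1 (0.165) or MT+/+ saline 2 (0.0843). Inflammation genes had 0.160 (10 of 16 positive, medians -0.05 and -0.01, camera adjusted p 0.0061, but adjusted p = 0.284 with an estimated correlation), lost without MT-/- DOX 1 (0.213) or MT+/+ saline 2 (0.0892). NRF2 targets had 0.0913 (12 of 18 positive, medians +0.29 and +0.37, camera adjusted p 0.0170, but adjusted p = 0.284 with an estimated correlation), lost with median centring (0.0592) and without MT-/- DOX 1 (0.113), MT-/- saline 1 (0.0623), MT+/+ DOX 2 (0.0700) or MT+/+ saline 2 (0.246).

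Oxidative phosphorylation genes had a median difference of -0.0801, with 4 of 34 positive (medians -0.10 and -0.17, camera adjusted p 9.1e-04, but adjusted p = 0.284 with an estimated correlation). The call was lost under the deposited scaling (-0.05, 0.238), under median centring (-0.03, 0.517), under cyclic loess, where the median was 4.0e-04 (0.892), and without MT+/+ saline 2 (0.0892). By fry the 7 lists other than the myeloid and fibroblast markers stood between 0.230 and 0.809.

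The myeloid lists were weighed against technical readings. A single array did not decide the direction: with each array left out in turn the macrophage median stayed between 0.358 and 0.459 and the neutrophil median between 0.0992 (without MT-/- DOX 1) and 0.363. Scaling did not decide it either, as under the other scalings the macrophage median was 0.333 to 0.351 and the neutrophil median 0.182 to 0.199. Residual blood in the hearts may contribute: 11 red cell, T cell and B cell markers had a median difference of 0.0767, with a 95% interval of 0.0078 to 0.174. That interval came from resampling the 11 genes and not the arrays, so it does not measure the spread between mice. Most of these markers lay near the floor, and the red cell gene Alas2 had -0.60. A candidate hypothesis is that hearts labelled MT-/- held more myeloid cells after DOX, and cell counts in tissue sections of both genotypes would test it.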

How the results depend on the processing

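The tests of removed Mt1 and Mt2 transcripts, exchanged labels and a strain segment were chosen only after the result was seen. A block by replicate number leaves each log2 change as it was, as every group holds both numbers, so only errors can change. All probe sets called unblocked were kept. Fatty acid oxidation for DOX in MT+/+ (0.0833) and metallothionein and zinc transport for genotype under DOX (0.0514) missed the list call. The counts of probe sets became 2740 for DOX in MT+/+ (613 unblocked), 4188 for DOX in MT-/- (1538), 6702 for DOX averaged (3433), 209 for genotype under saline (46), 383 for genotype under DOX (70), 1202 for genotype averaged (224) and 1 for the interaction (0). Besides the calls given in the report, the block changed only that of autophagy genes for genotype averaged (0.0617 to 0.0495).

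With only the compared groups in the fit, counts were 505 and 997 for DOX in MT+/+ and MT-/-, and 31 and 37 for genotype under saline and DOX. Requiring a change of at least 2-fold as well left 246 for DOX in MT+/+, 539 for DOX in MT-/-, 417 for DOX averaged and 76 for genotype averaged. Of the 85 calls by camera in the gene list tests, 0 remained with an estimated correlation, and the lowest adjusted p was 0.10. The scalings moved the median of all probe sets by at most 0.0227 from its value with quantile normalization.

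Leaving out 1 array gave counts of 46 (without MT+/+ DOX 2) to 771 for DOX in MT+/+, 383 (without MT-/- saline 1) to 1994 for DOX in MT-/-, and 1713 (without MT-/- saline 1) to 3829 for DOX averaged. For genotype they were 15 (without MT+/+ saline 1) to 50 under saline, 23 (without MT+/+ DOX 1) to 62 under DOX and 88 (without MT-/- saline 2) to 194 averaged. The interaction had 0 to 1, the 1 without MT+/+ saline 1, and the list calls numbered 71 to 91. The highest counts all came without MT-/- DOX 1, the list calls and the interaction apart.

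For the named genes, settings that kept all arrays gave the same outcome in 2137 of 2189 checks, a lost call in 43, a gained call in 8 and a turned sign with a new call in 1. Values without a call before or after changed sign in 47 further checks, those with 1 array left out included. The new call was Top2a for DOX averaged, at -0.67 (adjusted p 0.0092) as the mean of its probe sets against +0.01 for its brightest. The calls lost with the mean of probe sets are given in the report. Among the other losses, Tbc1d4 averaged over treatments missed the threshold under the deposited scaling (0.0541). With only the compared groups in the fit, Ahnak2 (0.0520) and Irx3 (0.0979) missed it for genotype under DOX, as did Nedd1 (0.0924), Mccc1 (0.0919), Pgap2 (0.0683) and Stk25 (0.0834). Under saline Atp10d, Adhfe1, Arhgap31, Stk25, Gdpd1 and Pgap2 missed it in that fit (0.0593 to 0.0891). Under the deposited scaling Ift81 (0.0538), Atp10d (0.0538), Arhgap31 (0.0662), Stk25 (0.0792) and Pgap2 (0.116) missed it under saline. For the lists 993 of 1157 checks gave the same outcome and 164 a lost call, most of them with an estimated correlation or by fry. Among the others, without the trend the call was missed by oxidative phosphorylation (0.0769) and glycolysis (0.0650) for DOX in MT+/+, by ribosomal genes for DOX in MT-/- (0.0553), and by cardiac stress (0.0618), fatty acid oxidation (0.0532) and ribosomal genes (0.130) for genotype under saline. Cardiac stress genes missed it there under cyclic loess too (0.0555). For genotype under DOX the metallothionein list missed it without a filter (0.0934) and with the stricter filter (0.0607), as neutrophil markers did with the stricter filter (0.131). With the mean of probe sets glycolysis for DOX in MT+/+ (0.0606) and ribosomal genes for genotype under saline (0.0818) missed it, and cell cycle genes for DOX in MT-/- did with only the compared groups in the fit (0.0814).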

Other observations

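Tests of removed Mt1 and Mt2 transcripts, exchanged labels and a strain segment, and their pattern, were chosen only after the result was seen. Several gene groups not given above also moved after DOX, averaged over genotypes. Genes of autophagy and proteolysis, which clear damaged parts of the cell, rose: 9 of 20 rose and 1 fell (10 and 1 over the list alone), median +0.27 (camera adjusted p 1.4e-04, but adjusted p = 0.155 with an estimated correlation). Sqstm1 (+1.22), Psmd4 (+1.13), Map1lc3b (+0.99) and Bnip3 (+1.39) rose and the protease Ctsb fell (-0.61). In MT+/+ the counts were 4 and 1 of 20 (camera adjusted p 5.2e-04, but adjusted p = 0.150 with an estimated correlation), and in MT-/- 6 and 1 (4.6e-05, but adjusted p = 0.170 with an estimated correlation). Circadian clock genes, which also answer to feeding, had 5 of 14 rising and 1 falling (6 and 1 alone), median +0.21 (camera adjusted p 0.0135, but adjusted p = 0.189 with an estimated correlation). The output genes Tef (+1.20), Dbp (+1.37) and Nr1d2 (+1.03) rose and the clock driver Arntl fell (-0.61), with list calls in MT+/+ (0.0076, but adjusted p = 0.150 with an estimated correlation) and MT-/- (0.0200, but adjusted p = 0.220 with an estimated correlation, and 0.108 with only these groups in the fit).

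Ribosomal protein genes, the core of protein synthesis, rose slightly: 4 of 20 rose and 0 fell (7 and 0 alone, 9 and 0 blocked), median +0.14 (camera adjusted p 2.0e-04, but adjusted p = 0.263 with an estimated correlation), with Rps9 at +0.45. They were called in MT+/+ (0 of 20 passed, 1 alone, 4 blocked, camera adjusted p 4.9e-05, but adjusted p = 0.258 with an estimated correlation) and in MT-/- (1 of 20, camera adjusted p 0.0111, but adjusted p = 0.404 with an estimated correlation). ER stress genes, which answer to misfolded protein, had 2 of 17 rising (the same alone, 5 blocked), Herpud1 (+1.4) and Dnajb9 (+0.75), median +0.18 (camera adjusted p 0.0354, but adjusted p = 0.203 with an estimated correlation). That call was lost without MT-/- DOX 1 (0.0816), MT-/- saline 2 (0.0600) or MT+/+ DOX 1 (0.0893) and with the mean of probe sets (0.0742), and in MT+/+ the list was called as well (0.0059, but adjusted p = 0.150 with an estimated correlation). Heat shock protein genes had 4 of 16 falling and 1 rising (5 and 1 alone, 6 and 3 blocked), median -0.29 with no call (adjusted p 0.0518). Hsph1 (-1.56), Dnaja1 (-1.04) and Hspe1 (-0.62) fell and Bag3 rose (+0.45), and in MT+/+ the list was called (0.0124, but adjusted p = 0.191 with an estimated correlation).

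The other lists had no call for DOX averaged. Of 12 iron genes 3 rose and 2 fell (the same alone), median -0.08 while camera pointed up (adjusted p 0.824), with the receptor gene Tfrc (-1.73) and Slc25a37 (-0.81) falling and Slc25a28 (+0.98) rising. Of 11 histone genes 1 rose and 1 fell (1 and 2 alone, 2 and 2 blocked), median -0.03 (adjusted p 0.605), H1f2 (+0.76) and H2az1 (-0.79). Of 22 DNA repair genes 1 rose, Xrcc5 (+0.55), and 1 fell, Chek2 (-0.64) (the same alone, 4 and 3 blocked), median 0.00 (adjusted p 0.605). Endothelial markers had 1 of 14 rising and 3 falling (2 and 3 alone, 3 and 4 blocked), median -0.12 (adjusted p 0.241), with Flt1 at +0.56, Cldn5 at -0.79, Emcn at -0.44 and Kdr at -0.72. Of 9 smooth muscle markers 3 fell, Acta2 (-1.46), Smtn (-0.62) and Tagln (-0.38), the same alone, median -0.12 (adjusted p 0.124). Of 7 adipocyte markers 2 rose, Lipe (+0.70) and Cidea (+0.68), the same alone, median +0.06 (adjusted p 0.235). Of 9 atrial markers 1 rose, Tbx5 (+0.49), and 1 fell, Myl1 (-1.83) (1 and 2 alone), median -0.10 (adjusted p 0.679), and of 5 skeletal muscle markers 0 passed (2 fell blocked), median -0.16 (adjusted p 0.431). Too few genes were measured to test markers of T cells (4), B cells (3), red cell precursors (4), lung (4), thymus (3) and liver (4). Among these Alas2 fell (-3.91) as did the liver gene Apoh (-0.50, adjusted p 0.0177), while Hba-a1 (+0.14, 0.283), Slc4a1 (-0.28, 0.107), Klf1 (-0.11, 0.472), Cd3e (-0.05) and Ighm (-0.14) did not pass.

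That Mt1 and Mt2 were not called lower on arrays labelled MT-/- was weighed against readings of the labels and the allele. The leading probe sets of both genes argue against an allele that removes both transcripts, under either reading of the labels. Their lowest signal on any array lay at percentile 90.1. Probe sequences were not examined, so signal from other transcripts is not ruled out. A dimmer Mt1 probe set lay between percentiles 39.8 and 57.9 and was not called between the genotypes. An error in the label of 1 array is not a likely explanation, as 0 of 8 arrays were placed with the other genotype by the 20 probe sets that best separated the other 7. A whole exchange of labels remains open, because on the arrays labelled MT+/+ the leading probe sets also reach down only to percentile 90.1. A hypothesis is that the altered allele is still transcribed and the protein is lost, and reading the allele from genomic DNA would test it.

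Genes near Mt1 and Mt2 were called for genotype more often than others. Of 131 tested genes within 200 genes of Mt1, 5 (3.82%) were called, against 109 of 12812 (0.851%) elsewhere, an odds ratio of 4.62 (95% interval 1.45 to 11.4, two-sided Fisher exact p 0.0060). They were Ndrg4 (-2.81, 62 genes after Mt1), Irx3 (-1.12, 43 before), Gadd45gip1 (-1.01, 190 before), Mmp2 (+1.0, 31 before) and Rnaseh2a (+0.57, 175 before). Over the whole chromosome of Mt1, 15 of 699 genes were called, an odds ratio of 2.69 (95% interval 1.44 to 4.69, two-sided Fisher exact p 0.0012). Il15, Calr3, Ocel1, Pdlim3 and Frg1 lie on it outside the band (gene order of assembly GRCm38.p6). For that rest of the chromosome the odds ratio was 2.11, with a 95% interval of 0.979 to 4.08 that includes 1 (two-sided Fisher exact p 0.0340), so the band is not set clearly apart from it. DOX calls were not enriched near Mt1 (odds ratio 1.04, exact p 0.902), and with the blocked calls the enrichment near Mt1 did not pass (odds ratio 1.61, 95% interval 0.747 to 3.08, exact p 0.152). A chromosome segment of another strain around the inactivated genes may therefore carry part of the difference.

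Probe sets that meet a sequence variant of 1 strain may give differences of single probe sets. For 50 called genes with other tested probe sets, these changed by a median of 0.394 (95% interval 0.146 to 0.612) in the called direction, against 0.864 for the probe set used, and 40 had the same direction and 22 a call of their own. For DOX calls the same medians were 0.340 and 0.548, so the data leave open how many genotype calls come from such variants. Zfp991 and Calr3, whose probe sets disagree in sign, are candidates, and sequencing of the transcripts would test this.

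Other splits of the 8 arrays into 4 and 4 were compared with the real ones. For DOX, with genotype as a term in each fit, only 1 of the 34 splits, the real one, gave as many probe sets (3886). The highest other gave 1. In the other splits all or part of the large DOX effect stayed in the unexplained spread and lowered their counts. That comparison therefore does not measure chance. For genotype, with treatment as a term, 2 of the 34 splits gave as many as the real 259, so over all splits chance is not excluded. The other of these, the highest with 1288, was the split by replicate number, which follows the pairing of the arrays. Among the 17 splits with both numbers equally on each side the real ones gave 3886 and 259 and the highest other 0 for each, and these splits are too few for a share under 0.05 for DOX and genotype alike. Replicate number 2 differed from number 1 in 3621 probe sets, 1949 higher and 1672 lower, with glucocorticoid and fasting genes higher (median +0.29, camera adjusted p 0.0016, but adjusted p = 0.915 with an estimated correlation). The actin 3' to 5' ratio was also higher in replicate 2 in 4 of 4 groups. The arrays thus hold a structure that follows the replicate number, which may be a shared day or batch, and the blocked fit called 1202 probe sets for genotype averaged.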
